A study of Mus musculus with 9 samples.

How the data were processed

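Total RNA of the dentate gyrus was extracted with a column kit from 9 individual C57BL/6 mice aged 8 weeks and sequenced on Illumina libraries, per the labels' protocols. The groups E0, E1 and E4, with 3 mice each, were taken from the sample titles. What was analysed here are 2 tables of the authors' own comparisons, E1 against E0 and E4 against E0. Reads were aligned with TopHat2 and compared with DESeq2 on the mouse build mm9, per the submitters' processing notes, which give no versions. The counting program, the annotation, the strand setting and the model formula are not given in the sources used here.

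The signal column of the deposited tables is the mean over the libraries of a comparison of counts divided by size factors, per the file headers (named mean count here), and each table has its own scale. The deposited log2 fold changes and their standard errors are the authors' estimates, named as by DESeq2 per the file headers. They appear shrunken toward 0, since genes with a mean count below 1 had a median absolute log2 fold change of 0.142 in the authors' table for E1 and 0.106 in that for E4. The score in the deposited tables is the log2 fold change over its standard error, and the deposited p-value is its two-sided normal p, with differences of at most 9.8e-08 and 5e-08 when recomputed. The authors' adjusted p-values equal Benjamini-Hochberg values over the genes that have one within 3.6e-07. Each table lists 24015 genes, of which 5929 in the table for E1 and 5718 in that for E4 have a mean count of 0, and 15660 and 14455 have an adjusted p. The lowest mean counts with an adjusted p were 1.301 and 4.579, and an adjusted p that is missing was kept missing. In the table for E1 27 symbols had been turned into dates by a spreadsheet, so 23988 symbols are shared. The dates were left out of gene lists, named genes and all steps that join both tables. They were kept in the totals of genes tested and called in E1 and in the median sizes of those calls.

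Counts per library were not used here, so no count test was run and the plan for tables of comparison statistics applied. A gene was called where the authors' adjusted p was below 0.05. The tables hold no value per mouse, so no SD is given and each value carries the authors' SE. Depth was approximated from the mean counts of genes with 1 read, which recur at 6 values per table, 3 for genes higher in E0 and 3 for genes higher in the other group. These steps give the size factors (0.932, 0.657 and 0.380 for E1 beside 2.140, 1.767 and 1.202 for E0), and a size factor times the sum of mean counts gives about the reads per library. Of genes with at most 4 reads, 1047 could be solved for whole reads in both tables, and all 1047 had the same E0 reads in both. Of these, 890 had at least 1 E0 read, and 143 of the 890 still matched after shuffling the genes. Both tables thus use the same libraries for that group. The deposited tables do not name the group, and it was taken as E0 because both share it.

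Before the data were examined, 38 gene lists were fixed: immediate early transcription factors, synaptic and secreted effectors, feedback regulators, neuropeptides, growth factors and receptors, DNA methylation, histone modifiers, glutamate receptors, GABA receptors, postsynaptic scaffolds, potassium channels, sodium and calcium channels, Wnt, Notch, glucocorticoid-responsive genes, heat shock, the unfolded protein response, inflammation, cholesterol synthesis, glycolysis, the respiratory chain, the circadian clock, the cell cycle, neural progenitors, and, for the rest, markers of cell types of the dentate gyrus and its surroundings. A list was tested with cameraPR of limma 3.58.1 (R 4.3.3) on the authors' statistic with a preset correlation of 0.01, adjusted over all lists and both comparisons. An estimated correlation and the rotation test fry need values per library and were not run. Members are those with an adjusted p, and counts adjusted over the list alone apply Benjamini-Hochberg to the members' deposited p-values.

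The genes named were also chosen by a rule fixed before the data were examined. It takes the 12 raised and 8 lowered called genes with the largest log2 fold change and a mean count of at least 50. Left out are histone, small RNA and ribosomal protein genes and symbols of Gm or LOC with a number or ending in Rik. It adds up to 4 members of each list described with the smallest adjusted p, and Fos, Arc, Npas4, Egr1, Bdnf, Homer1, Nptx2, Gadd45b and Frzb. For E4 against E1 it takes 6 genes each way. The values of 1 gene that the rule could name are not reported here.

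For E4 against E1 no test had been planned for tables of this kind. The difference of the deposited log2 fold changes was divided by the root of the sum of their squared SEs and compared with a normal distribution, over 12769 genes with a mean count of at least 10 in both tables. This was chosen after seeing the data. It ignores that both comparisons share E0, which taken alone would make it conservative. An alternative takes a share of 0.5 of the smaller variance as E0 error common to both. For the overlap of calls, 100 draws of unchanged groups with that shared part gave the values expected of shared controls alone. Transcript length, GC content and repeats came from the longest GENCODE vM21 transcript of a symbol, an annotation of another build than mm9, so no coordinates are given. The length and GC trend is a cubic fit on genes with a mean count of at least 10, in a form tried first and not centred, and in a centred form with fold changes held within 2 log2 units that was chosen after the first had been seen.

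The procedures were tested on simulated data with 200 changed genes. At a log2 change of 0.5, 1 and 2 the calls recovered 19.7%, 57.6% and 88.9% of the changed genes for E1 (15638 genes) and 50.0%, 77.4% and 100% for E4 (14433 genes). The difference test recovered 57.5% at a log2 change of 1, and its form with a shared error 72.0%. Among unchanged genes 1.34% and 4.92% passed the unadjusted level of 0.05. The simulated errors shared the same part of 0.5 that the second form removes, so these rates follow from the setting. They do not show how either form behaves on the deposited fold changes, which appear shrunken. The list test found the shifted list of immediate early transcription factors in 5 of 5 draws and called 0 of 185 tests of the other lists. Genes were drawn independently there, so errors from correlated genes were not tested. Far fewer genes were changed in the simulation than were called in the data. Its adjustment was therefore stricter, and recovery in the data may be higher.

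Alternatives planned before the data were examined were an adjusted p of 0.01 and 0.1, an absolute log2 fold change of at least 1, Benjamini-Hochberg adjustment over all genes with a p and over genes with a mean count of at least 10, and a rank-based cameraPR. Those chosen after seeing the data were genes with a mean count of at least 10 in both tables, a preset correlation of 0.05, genes with an annotated transcript, both forms of the trend over those genes and the variants of the difference test. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with random seed 1.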

Results

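RNA was measured in the dentate gyrus, the part of the hippocampus whose principal cells are granule neurons, microdissected from C57BL/6 mice aged 8 weeks. Libraries of total RNA came from individual mice, 3 in each of the groups E0, E1 and E4. The series asks how neuronal activation changes RNA expression and chromatin accessibility in the adult brain, and its labels give no unit for the number after E. As background to the study, the groups are mice before stimulation, 1 h after and 4 h after electroconvulsive stimulation, a treatment that makes granule neurons fire together. The values are those of the authors' deposited table for E1 against E0 and the authors' deposited table for E4 against E0, with a mean normalised count, a log2 fold change, its standard error (SE) and an adjusted p per gene.

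The depth of each library was approximated from the steps that single reads make in the mean counts of rarely read genes. The E0 libraries held about 6140000, 9090000 and 10960000 reads in genes, the E4 libraries about 10020000, 10230000 and 13550000. The E1 libraries were shallower, at about 1940000, 3360000 and 4760000 reads. The median SE of the log2 fold change over genes with a mean count of at least 50 was 0.17 for E1 and 0.135 for E4.

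**Figure D1:**
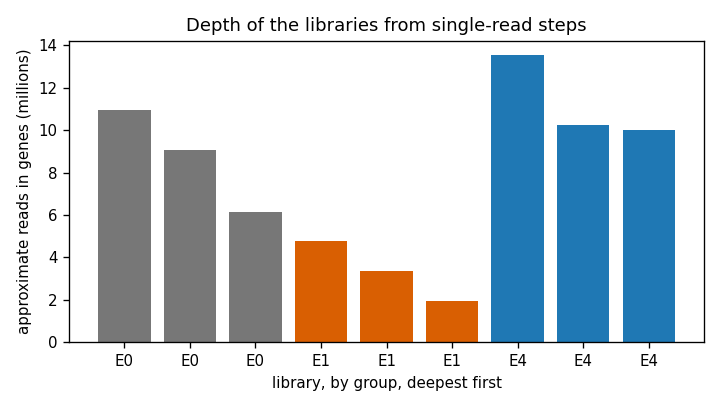
Approximate reads in genes (vertical axis, from 0) for each of the 9 libraries, by group and deepest first, with E0 as in the comparison with E4. The 3 E1 bars, from 1940000 to 4760000 reads, all lie below the 6 others.

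The comparison of E1 with E0 asks which transcripts had changed at the earlier time. The transcription factors of the immediate early response, which firing neurons switch on without new protein synthesis, rose together. Of 27 measured members 25 were raised and 2 not called. Their median log2 fold change was 2.98 (26 raised when adjusted over the list alone, cameraPR adjusted p = 7.5e-100). In the authors' deposited table Fosb stood at 6.92 ± 0.16 (log2 fold change ± SE), Nr4a2 at 5.92 ± 0.15, Nr4a3 at 4.86 ± 0.15 and Egr3 at 4.34 ± 0.09. Fos, a partner in the AP-1 complex and a widely used marker of recent firing, was raised 25-fold in the authors' deposited table (4.64 ± 0.21, adjusted p = 7.7e-110). Egr1 was raised there 13.1-fold (3.72 ± 0.16) and Npas4, a factor induced by calcium entry, 7.91-fold (2.98 ± 0.32), in the authors' deposited table.

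Synaptic and secreted products of activity rose as well, 24 of 30 members with 6 not called and a median of 2.33 (24 adjusted over the list alone, adjusted p = 5.1e-72). Arc, which takes part in the removal of AMPA receptors from synapses, was raised 101-fold in the authors' deposited table (6.65 ± 0.14, adjusted p listed as 0). The same holds for Homer1, a postsynaptic scaffold protein with a short activity-induced form, at 19.6-fold (4.30 ± 0.10) in the authors' deposited table. Ptgs2, the inducible cyclooxygenase, stood at 4.16 ± 0.11, the kinase gene Plk2 at 3.35 ± 0.10 and the pentraxin gene Nptx2 at 4.80 ± 0.17 in the authors' deposited table. Feedback regulators of kinase and cytokine signalling followed, 15 raised, 2 lowered and 7 not called of 24, median 1.32 (15 and 2 adjusted over the list alone, adjusted p = 1.5e-10). Spry2 at 2.55 ± 0.13, Errfi1 at 2.44 ± 0.14 and Sik1 at 2.84 ± 0.19 were among the raised members in the authors' deposited table.

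Among growth factors and their receptors 12 of 25 rose, 2 fell and 11 were not called, median 0.62 (12 and 3 adjusted over the list alone, adjusted p = 0.0117). Bdnf, a neurotrophin of synaptic plasticity, was raised 6.16-fold (2.62 ± 0.12), Vegfa stood at 1.81 ± 0.14 and Bmp4 at 4.01 ± 0.38 in the authors' deposited table. The mean count of Bmp4 was 56.83 in the authors' deposited table for E1. In that for E4 it was only 6.897, and Bmp4 was not called there. Heat shock proteins and chaperones rose in 15 of 18 cases with 3 not called, median 0.83 (15 adjusted over the list alone, adjusted p = 2.7e-10). Among them were Dnajb5 at 2.04 ± 0.14, Dnajb1 at 1.99 ± 0.14 and Hspa5 at 1.42 ± 0.11 in the authors' deposited table. Genes of cholesterol synthesis rose in 13 of 21 cases with 8 not called, median 0.50 (14 adjusted over the list alone, adjusted p = 0.0353). Cyp51, a sterol demethylase of that pathway, stood at 1.02 ± 0.12 in the authors' deposited table. With a preset correlation of 0.05 in place of 0.01 the calls of growth factors (adjusted p = 0.120) and cholesterol synthesis (adjusted p = 0.185) were lost.

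Markers of cell types moved in E1 as well. Of 17 GABAergic interneuron markers 10 rose and 7 were not called, median 0.70 (11 adjusted over the list alone, adjusted p = 0.0117, and 0.0826 with a preset correlation of 0.05). Other lists hold 5 of the 17 as well. The GABA-synthesising enzyme gene Gad2 stood at 1.57 ± 0.12, the vesicular GABA transporter gene Slc32a1 at 1.25 ± 0.15 and Lhx6 at 1.35 ± 0.22 in the authors' deposited table. Astrocyte markers fell in 12 of 16 cases with 4 not called, median -0.44 (12 adjusted over the list alone, adjusted p = 0.000693). Aldh1l1 stood at -1.09 ± 0.15, Gfap at -0.95 ± 0.14 and Aldoc at -0.67 ± 0.11 in the authors' deposited table. Of 15 granule neuron markers 9 fell, 4 rose and 2 were not called, median -0.54 (9 and 4 adjusted over the list alone, adjusted p = 0.0101). Dsp at -2.41 ± 0.14, Lct at -1.41 ± 0.14 and Bcl11b at -1.17 ± 0.12 were lowered in the authors' deposited table. Nrn1, also listed as an activity-induced gene, was raised at 1.07 ± 0.09 in the authors' deposited table. The granule call was lost with a preset correlation of 0.05 (adjusted p = 0.0631) and with the rank-based form (adjusted p = 0.143). Nuclear genes of the mitochondrial respiratory chain fell in 11 of 28 cases with 17 not called, median -0.21 (11 adjusted over the list alone, adjusted p = 0.0117). Ndufa4 stood at -0.67 ± 0.10 and Ndufb9 at -0.68 ± 0.12 in the authors' deposited table. That call was lost with a preset correlation of 0.05 (adjusted p = 0.131) and once a centred trend on transcript length and GC content was removed (adjusted p = 0.185).

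Single genes are ranked here and below among those that the naming rule keeps, so symbols such as those ending in Rik are left out. Of the 12 with the largest rises in E1, 10 had a mean count under 1 in the table for E4, so no fold is given for them. In the authors' deposited table for E1 the mean counts were 441 for the serine protease inhibitor gene Serpina1a, 295.6 for Cyp4a31, 629.5 for the potassium channel gene Kcnj15, 307.6 for the transcription factor gene Runx3, 238.2 for Hspb7 and 151.7 for Acnat1. Cer1 (180.9), Dkk1 (168.6), Pax3 (128.9) and Hoxd11 (128.2) completed them in the authors' deposited table for E1, and with Cyp4a31 these are listed at 0 in the table for E4. Tmem220 had a mean count of 934 in the authors' deposited table for E1 and 8.27 in that for E4, and Fosb was the remaining gene. Such genes numbered 184, and their transcripts often hold a CA or GA repeat or a B1 element, 22 of 40 among those not used to choose these repeats after the data were seen, against 12 of 120 silent genes of the same length. Serpina1a, Cyp4a31 and Acnat1 belong to families with close copies, so reads could have been split among them. The 8 largest falls in the authors' deposited table included those of Wnt9a at -3.02 ± 0.35, Dclk3 at -2.50 ± 0.24, Zcchc5 at -2.47 ± 0.30 and Dsp. The others in the authors' deposited table were Kirrel2 at -2.31 ± 0.23, the interleukin-1 receptor gene Il1r1 at -2.23 ± 0.21, Fam160a1 at -2.21 ± 0.24 and Glp2r at -2.15 ± 0.19. Frzb, a secreted Wnt antagonist, was lowered at -0.57 ± 0.15 in the authors' deposited table.

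In all, 5566 of 15660 genes tested passed the authors' adjusted p of 0.05 in E1, 3224 raised and 2342 lowered, so that 57.9% of the calls were rises. Part of that excess lay in genes of low count. With only genes of a mean count of at least 10 in both tables, 2701 were raised and 2310 lowered in E1 (53.9% rises). The share in E4 was then 52.5%. Of the genes tested, 14891 had an annotated transcript, with 3066 raised and 2242 lowered when adjusted among themselves (57.8% rises). Removing a trend on transcript length and GC content from the same genes gave 2738 raised and 2167 lowered in a centred form (55.8% rises), and 2169 raised and 3442 lowered without centring (38.7% rises). The form without centring moved the median log2 fold change of genes with a mean count of at least 10 from -0.006 to -0.171, against a move from -0.002 to -0.006 in E4. The list calls above were made relative to the other genes, and that form left all 10 of them in place. The median absolute log2 fold change was 0.977 for rises and 0.662 for falls, and 648 rises and 20 falls were of at least 2. The 184 genes with a mean count under 1 in the table for E4 are 28.4% of those 648 rises, and 88 of the 190 rises of at least 4.

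**Figure D2:**
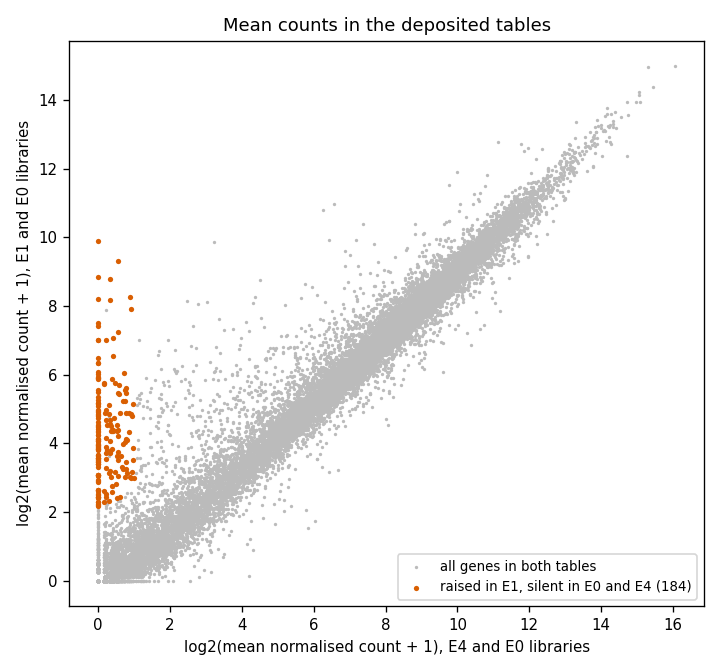
Each point is a gene, with the log2 of its mean normalised count plus 1 over the E4 and E0 libraries (horizontal) and over the E1 and E0 libraries (vertical). Orange points are the 184 genes raised by at least 2 log2 units in E1 with a mean count under 1 in the table for E4, which stand above the left end of the diagonal.

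The comparison of E4 with E0 asks which transcripts differed at the later time. Activity-induced synaptic and secreted products were still raised, 27 of 30 members with 1 lowered and 2 not called, median 1.59 (28 and 1 adjusted over the list alone, adjusted p = 4.5e-38). Sorcs3, a sorting receptor gene, was raised 14.7-fold in the authors' deposited table (3.88 ± 0.15, adjusted p = 3.0e-143), Nptx2 8.55-fold (3.10 ± 0.15) and Arc 10.7-fold (3.41 ± 0.33). Rgs4, a regulator of G protein signalling, stood at 2.32 ± 0.09, the secreted neuropeptide precursor gene Vgf at 2.31 ± 0.12, Homer1 at 1.18 ± 0.12 and Bdnf at 0.44 ± 0.12 in the authors' deposited table.

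Of 27 immediate early transcription factors 13 rose, 2 fell and 12 were not called in E4, median 0.68 (15 and 2 adjusted over the list alone, adjusted p = 6.0e-11). Klf10 was raised 16.5-fold (4.05 ± 0.13), Egr3 stood at 2.30 ± 0.10 and Ier5 at 2.44 ± 0.12 in the authors' deposited table. Egr1 was still raised at 0.71 ± 0.12, while Fos (0.51 ± 0.30, adjusted p = 0.169) and Npas4 (0.33 ± 0.30, adjusted p = 0.427) were not called in the authors' deposited table. Feedback regulators rose in 10 of 24 cases with 1 lowered and 13 not called, median 0.47 (12 and 1 adjusted over the list alone, adjusted p = 0.000501). Raised members included the phosphatase gene Dusp14 at 2.79 ± 0.11, Trib2 at 2.54 ± 0.13 and Sik1 at 1.34 ± 0.15 in the authors' deposited table. Heat shock proteins and chaperones rose in 11 of 18 cases with 2 lowered and 5 not called, median 0.39 (11 and 2 adjusted over the list alone, adjusted p = 0.000251). Dnajb5 stood at 2.05 ± 0.10 and Hsph1 at 2.07 ± 0.12 in the authors' deposited table.

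Genes of DNA methylation and demethylation rose in 7 of 17 cases in E4 with 1 lowered and 9 not called, median 0.27 (7 and 1 adjusted over the list alone, adjusted p = 0.00506, and 0.115 in the rank-based form). Gadd45b, which takes part in activity-induced demethylation in these neurons, was raised 11.9-fold (3.57 ± 0.18) in the authors' deposited table. The methylcytosine dioxygenase genes Tet3 at 1.43 ± 0.12 and Tet2 at 1.25 ± 0.15 and the methyltransferase gene Dnmt3a at 0.93 ± 0.10 were raised in the authors' deposited table. In E1 the same list had 5 raised, 2 lowered and 10 not called of 17 and no call (adjusted p = 0.307), with Gadd45b at 4.59 ± 0.21 and Gadd45g at 1.97 ± 0.17 in the authors' deposited table.

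The other lists called in E1 were not called in E4. GABAergic interneuron markers had 2 raised, 1 lowered and 14 not called of 17 (adjusted p = 0.733). Astrocyte markers had 1 raised, 4 lowered and 11 not called of 16 (adjusted p = 0.455), and respiratory chain genes 3 raised, 4 lowered and 21 not called of 28 (adjusted p = 0.927, 3 and 2 adjusted over the list alone). Granule neuron markers went both ways, 7 raised, 6 lowered and 2 not called of 15 (adjusted p = 0.102). Tdo2, an enzyme of tryptophan breakdown, stood at -4.0 ± 0.18, C1ql3 at -1.23 ± 0.09 and Nrn1 at 1.69 ± 0.10 in the authors' deposited table. Growth factors and receptors had 8 raised, 3 lowered and 12 not called of 23 (adjusted p = 0.0728). The activin receptor gene Acvr1c stood at 3.31 ± 0.12 and the neurotrophin gene Ntf3 at -2.02 ± 0.19 in the authors' deposited table. Cholesterol synthesis genes had 7 raised, 2 lowered and 12 not called of 21 (adjusted p = 0.408). The regulator gene Srebf2 stood at 0.88 ± 0.09 and Ebp at 1.32 ± 0.15 in the authors' deposited table. Whether these lists differed between E4 and E1 was not tested.

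Besides Klf10, Sorcs3, Gadd45b and Arc, the largest rises in E4 were those of the keratin gene Krt75 at 4.71 ± 0.38, Tll1 at 4.46 ± 0.23, the retinoic acid receptor gene Rara at 3.98 ± 0.19 and the prolactin receptor gene Prlr at 3.71 ± 0.34 in the authors' deposited table. The transcription factor gene Tbx21 at 3.63 ± 0.33, Pmepa1 at 3.62 ± 0.12, Serinc2 at 3.48 ± 0.24 and C2cd4a at 3.38 ± 0.20 followed in the authors' deposited table. Krt75 and Tbx21 had mean counts of 65.11 and 55.96 in the authors' deposited table for E4. In that for E1 these were 2.331 and 1.902, so both genes were little read in E0 and E1. Falls were largest for Tdo2, then Zcchc5 at -3.41 ± 0.25, the matrix protein gene Ogn at -3.39 ± 0.24, Plekhd1 at -2.90 ± 0.21 and the neuropeptide Y receptor gene Npy2r at -2.86 ± 0.14 in the authors' deposited table. Acot5 at -2.69 ± 0.28, Wnt9a at -2.64 ± 0.23 and Fam84b at -2.63 ± 0.15 completed the 8 in the authors' deposited table, where Frzb stood at -1.39 ± 0.13. Acot5 also has close copies that could share its reads. In all, 5639 of 14455 genes tested were called in E4, 2989 raised and 2650 lowered (53.0% rises), with median absolute log2 fold changes of 0.568 and 0.606 and 105 rises and 27 falls of at least 2.

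**Figure D3:**
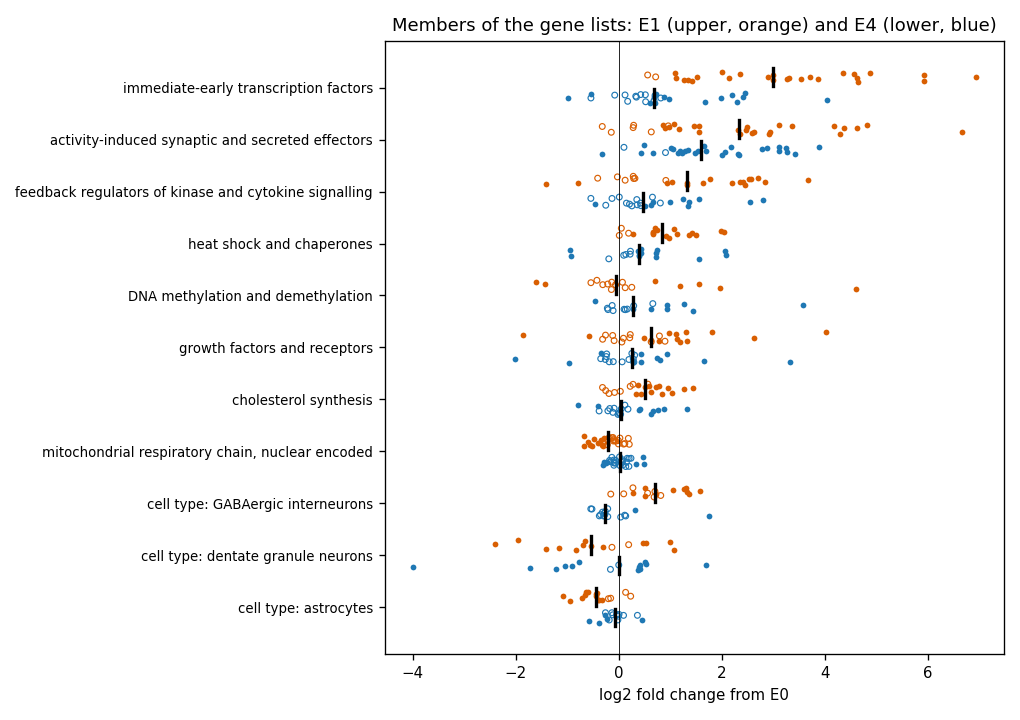
Log2 fold changes from E0 (horizontal) of the measured members of the 11 gene lists called in either comparison, E1 above in orange and E4 below in blue. Filled points passed the adjusted p of 0.05, open points did not, and black bars mark medians, which for the immediate early transcription factors are 2.98 in E1 and 0.68 in E4.

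The change from E1 to E4 was tested, by a method chosen after the data were seen, as the difference of both deposited log2 fold changes over their combined error. Of 12769 genes 2256 were higher and 2425 lower in E4 than in E1. The test leaves out genes with a mean count under 10 in either table, among them Serpina1a, Kcnj15 and Runx3. Among genes with a mean count of at least 50 in both tables, 4 of the 6 largest drops were those of immediate early transcription factors, with Nr4a2 at 5.92 ± 0.15 in E1 and -0.54 ± 0.23 in E4 and Fosb at 6.92 ± 0.16 and 0.97 ± 0.24 in the authors' deposited table. Nr4a3 went from 4.86 ± 0.15 to -0.99 ± 0.24, Egr4 from 4.57 ± 0.17 to 0.17 ± 0.21 (not called) and the kinase inhibitor gene Pkib from 3.71 ± 0.36 to -1.19 ± 0.26 in the authors' deposited table. Kcnq1ot1, a noncoding RNA antisense to Kcnq1 whose reads may not be separable from those of Kcnq1 because strand use in counting is not stated, went from 5.30 ± 0.17 to 0.85 ± 0.21 in the authors' deposited table. The largest gains among such genes were those of Dusp14, at -0.80 ± 0.20 in E1 and 2.79 ± 0.11 in E4, and Fam43b, at -0.21 ± 0.26 (not called) and 3.30 ± 0.15, in the authors' deposited table. Pdzd2 (-2.14 ± 0.18 and 1.29 ± 0.10), Rasl10a (-1.60 ± 0.17 and 1.79 ± 0.11) and Grm2, a presynaptic glutamate receptor (-2.09 ± 0.18 and 0.95 ± 0.12), were lowered in E1 and raised in E4 in the authors' deposited table. Sorcs3 was at 0.85 ± 0.20 in E1 in the authors' deposited table, against 3.88 in E4.

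Among the 14390 genes tested in both comparisons, 973 were raised in both and 786 lowered in both, against 583.8 and 429.4 for independent lists. Opposite calls were fewer than for independent lists, 369 raised in E1 and lowered in E4 (520.9) and 381 lowered in E1 and raised in E4 (481.2). A further 1494 genes were raised and 1171 lowered in E1 alone, of which 1009 and 715 also passed the difference test. Another 1608 were raised and 1488 lowered in E4 alone, of which 851 and 683 passed it. The log2 fold changes correlated across genes at r = 0.229, where genes are not independent replicates. Both comparisons share the E0 libraries, and unchanged groups simulated against shared controls over the same 14390 genes gave r = 0.380. No gene was called in both there, which follows from simulating no changed gene. The covariance was 0.1027 observed and 0.0253 simulated, a difference of 0.0774. The same sign was found for 57.9% of genes and for 62.5% in the simulation. The simulated r and share of signs come from error alone and are no yardstick for data with many changed genes. That the observed values are lower therefore does not show less agreement than shared controls would give. Part of the overlap may come from the shared controls, which were not split because the tables hold no value per library.

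**Figure D4:**
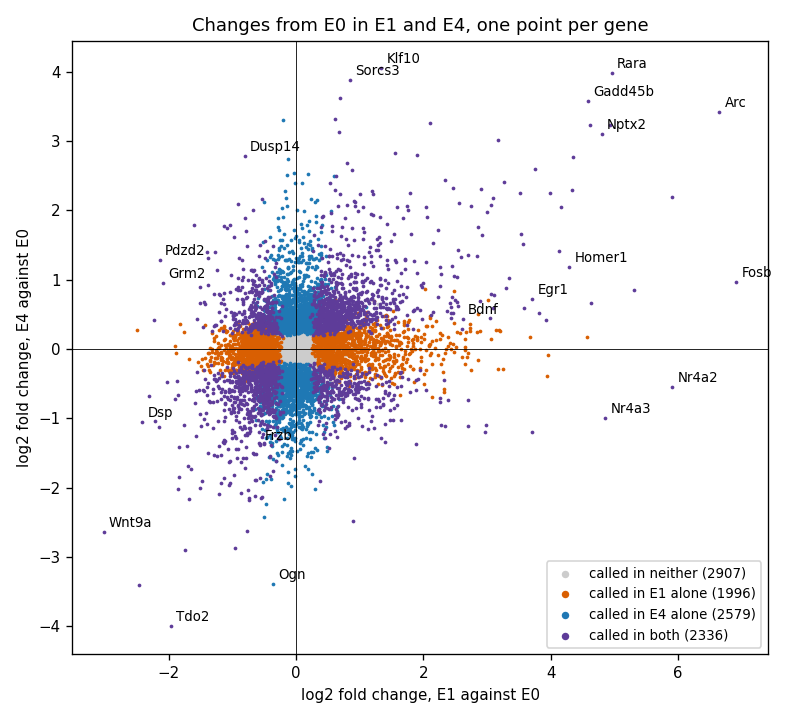
Each point is one of 9818 genes with a mean count of at least 50 in both tables, by its log2 fold change from E0 in E1 (horizontal) and in E4 (vertical). Purple points (2336) were called in both comparisons, orange points (1996) in E1 alone, blue points (2579) in E4 alone and grey points (2907) in neither, and Nr4a2 and Nr4a3 lie to the right and below 0.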

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

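The difference test between E4 and E1, the tests of repeats in the genes not used to choose them, of a single library, of Hox neighbours, of genes switched on in E1, of the granule share and of the centred trend were chosen only after the result was seen. Groups of 3 mice are not tested for single samples that stand apart. Of 90 genes named in the text that could be tested, 80 differed between E4 and E1 (adjusted p below 0.05), 46 lower and 34 higher in E4. These genes were named mostly for large or highly significant changes, some for this difference itself, so that share is not typical, and over all genes 4681 of 12769 differed. The differences that follow are E4 minus E1, from the log2 fold changes of the authors' deposited tables. Lower in E4 by the most were Nr4a2 -6.46, Fosb -5.95, Nr4a3 -5.85, Pkib -4.90, Kcnq1ot1 -4.46, Egr4 -4.40, Fos -4.13, Arc -3.24. Then came Homer1 -3.11, Ogn -3.03, Egr1 -3.00, Kcnc2 -2.77, Npas4 -2.66, Per1 -2.49, Plk2 -2.34, Nfil3 -2.20. After these stood Bdnf -2.19, Ptgs2 -2.12, Egr3 -2.05, Tdo2 -2.03, Spry2 -1.94, Errfi1 -1.92, Npy2r -1.91, Fam84b -1.86. Below them were Tbr1 -1.81, C1ql3 -1.76, Kcnv1 -1.72, Nptx2 -1.71, Per3 -1.60, Dnajb1 -1.56, Slc32a1 -1.55, Gad2 -1.54. They were followed by Sik1 -1.50, Acot5 -1.29, Hlf -1.25, Lhx6 -1.24, Plekhd1 -1.16, Hspa5 -1.05, Gadd45g -1.04, Gadd45b -1.02. Smaller drops were those of Kdm6b -0.98, Rara -0.97, Zcchc5 -0.94, Frzb -0.82, Cyp51 -0.64, Vgf -0.59. Higher in E4 by the most were Dusp14 3.58, Fam43b 3.51, Pdzd2 3.43, Rasl10a 3.38, Grm2 3.05, Sorcs3 3.04, Pmepa1 2.94, Bhlhe41 2.87, Dclk3 2.78. Next were Klf10 2.71, Acvr1c 2.69, Il1r1 2.64, Trib2 2.57, Tll1 2.12, C2cd4a 1.98, Serinc2 1.87, Kirrel2 1.63, Bcl11b 1.57. In turn came Dsp 1.36, Gfap 1.30, Fam160a1 1.18, Tet3 1.18, Hsph1 1.15, Ebp 1.11, Dnmt3a 1.08, Glp2r 1.03, Rbpj 1.0. Smaller gains were those of Aldh1l1 0.90, Ndufb9 0.75, Nrn1 0.63, Aldoc 0.53, Ndufa4 0.50, Srebf2 0.50, Lct 0.49.

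A set of 184 genes was raised by at least 2 log2 units in E1 (median mean count 16.1, from 3.55 to 951.8, in the authors' deposited table) but had a mean count under 1 in the table for E4, which covers the E0 and E4 libraries, against 4 genes the other way round. One aberrant library is argued against for genes with a mean count of 5 to 60 in the table for E1 and 0 in that for E4. Of 75 such genes with recoverable reads 69 (0.920) had reads in all 3 E1 libraries, as did 67 of the 68 in the set. They were taken whether called or not because a call itself favours reads in several libraries. Outside the set only B020014A21Rik and Skint4 had reads in all 3. Members with a higher mean count, such as Serpina1a (441), were not examined. RNA of another organ is argued against by only 2 of 42 abundant organ transcripts (0.048) reaching their median, and a Hox-expressing tissue by 0 of 6 neighbouring Hox genes (0.000) having a mean count of at least 10. Repeats inside the transcripts are a candidate source: 22 of 40 genes not used to choose the repeats hold a CA or GA repeat or a B1 element, against 12 of 120 silent genes of the same length (ratio 5.50, Fisher's exact p = 1.9e-08), while the ratio of 4.57 over all 171 genes with a transcript is partly circular. The repeat-linked rise was not confined to the set. Over 9435 genes with a mean count of at least 50 in both tables, log2 fold changes were compared with and without a repeat. In E1 the median difference over 10 length classes was 0.108, above 0 in 10 of them. In E4 it was 0.001, above 0 in 5. Genes switched on in E1 and off again by E4 cannot be told apart from a feature shared by the E1 libraries, since such a feature would coincide with the group, the labels give no library batch, and 92 of the genes have a mean count above 0 in the table for E4.

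The 80 ribosomal protein genes measured, a group chosen after the data were seen, had a median log2 fold change of -0.61 in E1 (69 lowered, 1 raised, 10 not called) and 0.12 in E4 (20 raised, 1 lowered, 59 not called). A length and GC trend as the whole cause is argued against by a median of -0.42 (quartiles -0.67 and -0.27) after the centred trend was removed. That form took part of the fall away. Without centring the median was -0.64, but this form also lowered genes in general, whose median moved from -0.006 to -0.171. The value of -0.64 therefore does not show that the trend explains none of the fall. The fall was not limited to members of low count, with a median of -0.61 among the 76 with a mean count of at least 200. These are nearly all of the 80, so their median had to lie close to that of the whole group. The test therefore cannot decide on low depth. Low depth, another feature shared by the E1 libraries, for which the labels give no batch, and a response to stimulation stay open, as all would coincide with the group.

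Interneuron markers, raised in E1, are weighed as a change in tissue composition. A smaller share of granule cells should raise all other types, and the first bound set for it left the question open, with 2 of 9 other cell type medians below -0.2 and 6 of 9 above 0 (3 and 7 of 12 with choroid plexus, thalamus and habenula, and red blood cells, which it did not count). A second bound, chosen after that, used the astrocyte list, which was lowered with an upper quartile of -0.30. A smaller granule share alone would not lower these markers. The fall was known when the bound was chosen, however, and 1 list can also fall for a reason of its own, so this bound cannot decide. Repeats and the trend are argued against by a median of 0.70 (quartiles 0.49 and 1.05) among the 13 of 17 markers without a repeat and by medians of 0.58 (not centred, adjusted p = 0.00731) and 0.80 (centred, adjusted p = 0.0054). Interneuron markers were not alone in rising. In E1 the medians were 0.74 for CA3, CA2 and mossy neurons, 0.57 for CA1 and subiculum neurons and 0.54 for endothelial cells. These lists were not called, and the medians below -0.2 are counted above. Another tissue composition of the E1 dissections, in interneurons or more widely, stays open, a smaller granule share included. A feature shared by the E1 libraries and a response of interneurons to stimulation stay open as well.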

How the results depend on the processing

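The alternatives with a trend on transcript length and GC content, only genes with an annotated transcript, a preset correlation of 0.05, genes with a mean count of at least 10 in both tables and all forms of the difference test were chosen after seeing the data. The counts of calls stayed within 1.5 times the main value at an adjusted p of 0.1, with Benjamini-Hochberg adjustment over all genes or over genes with a mean count of at least 10, and with genes above that mean in both tables. With an absolute log2 fold change of at least 1, 2018 genes were called in E1 (1574 raised, 444 lowered) and 1024 in E4 (566 raised, 458 lowered), which follows from the added minimum. At an adjusted p of 0.01 the overlap of calls between E1 and E4 in the same direction was 1169 genes (1759 at 0.05). Genes called in opposite directions were then 425 (750) and those lowered in both 467 (786). In the difference test with an absolute difference of at least 1, 1982 of 4681 genes passed, 742 higher and 1240 lower in E4. With the trend removed and not centred the calls in E1 turned to 38.7% rises, from 57.8% among the same genes with an annotated transcript. The centred form gave 55.8%. The form without centring also removes the mean fold change. It moved the E1 median of genes with a mean count of at least 10 from -0.006 to -0.171, against -0.024 with centring. The turn to 38.7% thus goes with an offset of genes in general and is not evidence of a length or GC effect. With a preset correlation of 0.05 the E1 calls of interneuron markers (adjusted p = 0.0826), granule markers (0.0631), cholesterol synthesis (0.185), growth factors (0.120) and the respiratory chain (0.131) were lost. Those of astrocyte markers and of 4 raised lists held. In the rank-based form the granule markers (0.143) and, in E4, DNA methylation (0.115) were lost and microglia in E1 were gained as lowered (0.0264). The centred trend ended the call of the respiratory chain (0.185) and added glycolysis as raised in E1 (0.0162). No list turned its direction among called lists in these settings. No paired analysis was possible because the tables hold no value per mouse. For the same reason leaving out replicates, refits of 2 groups, other splits of the samples, tests on counts or on normalised values, an estimated correlation and fry were not run. Of genes simulated with a log2 change of 0.5 and each table's own errors, 14 of 71 were recovered in E1 and 35 of 70 in E4. How much of this comes from the lower depth of the E1 libraries was not separated from the spread between libraries.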

Other observations

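The group of Gm symbols and the correlations with length and GC content were chosen only after the data were seen, and the gene lists were fixed before. Circadian clock genes moved in both directions, 8 raised and 5 lowered of 19 in E1 (adjusted p = 0.169) and 7 and 7 in E4 (0.455). In the authors' deposited table Per1 at 2.27 ± 0.13 and Nfil3 at 2.89 ± 0.18 were raised in E1, Bhlhe41 at 2.74 ± 0.12 in E4, and the transcription factor gene Hlf at -1.89 ± 0.10 and Per3 at -2.15 ± 0.17 were lowered in E4. Histone modifiers and remodelers had 6 raised and 6 lowered of 30 in E1 (0.963) and 15 and 7 in E4 (0.455). The histone demethylase gene Kdm6b was raised at 3.06 ± 0.15 and 2.08 ± 0.14 in the authors' deposited table. Notch signalling had 3 raised and 4 lowered of 20 in E1 (0.581) and 4 and 4 in E4 (0.455), with Rbpj, its DNA-binding partner, at 1.05 ± 0.16 and 2.05 ± 0.12 in the authors' deposited table. Wnt signalling had 8 and 3 of 30 in E1 (0.558) and 7 and 4 of 27 in E4 (0.903). Neural progenitor and immature neuron genes had 4 and 4 of 19 in E1 (0.844) and 2 and 5 of 18 in E4 (0.408). Sox11 was raised at 1.8 ± 0.16 and 2.26 ± 0.14 and Tbr1 was lowered at -1.93 ± 0.14 in E4 in the authors' deposited table.

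Receptors and channels were not called as lists. GABA receptors had 6 raised and 2 lowered of 14 in E1 (0.625) and the same counts in E4 (0.570), and Gabrd, a subunit of extrasynaptic receptors, was lowered at -1.65 ± 0.17 and -1.74 ± 0.12 in the authors' deposited table. Glutamate receptors had 8 and 2 of 22 in E1 (0.570) and in E4 (0.501). Potassium channels had 8 and 6 of 25 in E1 (0.570) and 7 and 12 in E4 (0.608), with Kcnc2 at 2.33 ± 0.15 in E1 and Kcnv1 at -1.42 ± 0.15 in E4 in the authors' deposited table. Sodium and calcium channels had 11 and 2 of 26 in E1 (0.455) and 7 and 6 in E4 (0.903), and postsynaptic scaffolds 5 and 5 of 22 in E1 (0.454) and 11 and 3 in E4 (0.0532). Some E1 medians changed sign once the trend was removed and not centred, a form that also lowered genes in general. They went from 0.25 to -0.10 for GABA receptors (0.02 centred), 0.30 to -0.01 for glutamate receptors (0.13 centred) and 0.28 to -0.11 for potassium channels (0.02 centred). The clock went from 0.17 to -0.01 (0.13 centred) and scaffolds from 0.05 to -0.21 (-0.09 centred). Of these lists only scaffolds changed sign in the centred form. The centred form also turned Notch from -0.10 to 0.04.

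The other lists were not called either. Neuropeptides had 4 raised and 2 lowered of 18 in E1 (adjusted p = 0.733) and 3 and 2 of 19 in E4 (0.959). Glucocorticoid-responsive genes had 6 and 6 of 18 (0.307) and 4 and 4 (0.55), the unfolded protein response 6 and 0 of 17 (0.354) and 4 and 2 (0.608), and inflammatory genes 4 and 0 of 7 (0.649) and 2 and 0 (0.585). Glycolysis had 8 and 2 of 21 (0.233) and 6 and 4 of 20 (0.733), and the cell cycle 2 and 3 of 19 (0.501) and 3 and 2 of 18 (0.908). CA1 and subiculum markers had 5 and 1 of 12 (0.548) and 1 and 2 of 11 (0.891), and CA3, CA2 and mossy cell markers 7 and 3 of 14 (0.524) and 1 and 5 (0.122). Oligodendrocyte markers had 5 and 2 of 16 (0.733) and 1 and 0 (0.802), their precursors 0 and 1 of 12 (0.545) and 0 and 1 (0.585), and microglia 0 and 6 of 17 (0.0747) and 0 and 2 (0.585). Endothelial markers had 5 and 1 of 15 (0.548) and 0 and 0 (0.908), mural cells 2 and 1 of 12 (0.798) and 1 and 0 (0.908), and meningeal fibroblasts 0 and 0 of 12 (0.733) and 0 and 2 (0.318). Choroid plexus and ependyma had 0 and 2 of 11 (0.585) and 1 and 0 of 6 (0.751), thalamus and habenula 2 and 0 of 10 (0.424) and 2 and 0 (0.570), and red blood cells 0 and 2 of 3 (0.454) and 0 and 0 (0.733).

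Adjusted over the list alone, the counts of these lists were the same except in E1 for CA3 (8 and 3), endothelial (6 and 1), oligodendrocyte (7 and 2), precursor (0 and 0), microglia (0 and 7), choroid (0 and 1), scaffold (7 and 5), unfolded protein (7 and 1), potassium (10 and 6) and sodium and calcium channel lists (12 and 2). In E4 they differed for Wnt (8 and 4), glycolysis (7 and 4), scaffolds (11 and 4), microglia (0 and 1), mural cells (0 and 0) and precursors (0 and 0). Median, mean and test differed in sign in E1 for DNA methylation (-0.07, 0.32, up), meningeal fibroblasts (0.02, 0.01, down) and histone modifiers (-0.03, 0.10, down). In E4 they differed for the cell cycle (0.02, 0.05, down), endothelial cells (0.06, 0.01, down), the respiratory chain (0.01, 0.02, down), thalamus and habenula (-0.05, 0.14, up) and neuropeptides (-0.11, 0.11, down). Genes with a symbol of Gm and a number, a group chosen after the data were seen, had 124 raised and 10 lowered of 343 in E1 and 17 and 22 of 227 in E4. Across expressed genes the E1 log2 fold change correlated with transcript length at Spearman's rho 0.235 and with GC content at -0.239 over 9602 genes, against 0.082 and -0.098 over 10628 genes in E4, and genes are not independent replicates.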
